A study of Mus musculus with 26 samples.

How the data were processed

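RNA was measured by sequencing in 26 mouse libraries from a study of chemical reprogramming, in which fibroblasts are turned into pluripotent stem cells with small molecules. Per the labels, total RNA was extracted with TRIzol, libraries were made with a TruSeq RNA kit and read on a NextSeq 500. The submitters' processing notes name bcl2fastq, Bowtie2, RSEM and the mm10 genome, with no versions, annotation, normalization or filter stated.

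The authors deposited 1 table of 16718 genes by 26 libraries. The deposited values are treated here as a score, quantile-normalized by the authors to 1 common distribution and rounded to whole numbers. The table's name says CPM (counts scaled to library size), and the design written before the data were examined assumed that unit. The values contradict it, because every library sums to between 4143561 and 4162600, has a median of 77 (76 in CiPSC 5) and has a maximum of 21988. In each library exactly 10 genes hold that maximum, so a gene at the ceiling cannot show a further rise. Sequencing depth is therefore unknown, no interval or detection floor that needs counts can be given, and a count test could not be run because whole reads cannot be recovered. The share of genes listed at 0 was 5.59% to 10.8% in MEF and the courses and 10.4% to 14.2% in CiPSC. Of the gene names, 3 occur more than once and 23 look like dates, and all were kept as they stand. GENCODE M21 gave positions, lengths and GC content.

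The libraries fall into 5 groups. MEF (mouse embryonic fibroblasts, day 0) has 1 library. A course with all chemicals has 1 library on each of days 6, 12, 18, 22, 30, 36 and 40. A course without BrdU (bromodeoxyuridine, a thymidine analogue) has 1 library on the same 7 days. A course without Chir (an inhibitor of the kinase GSK3, used to activate Wnt signalling) has 1 library on each of the 5 days from 6 to 30. CiPSC (established chemically induced pluripotent stem cells) has 6 libraries. No arm has more than 1 library on a day, so days served as the only repeats, and the residual spread holds real change with time as well as noise. Successive days of a course are not independent, so p-values over days can be too small. They do not speak for a repeat of the course in another culture. The labels give no sequencing batch, and whether the CiPSC libraries were made together with the courses cannot be told apart from their group.

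Values were analysed as log2(value + 1) in R 4.3.3 with limma 3.58.1, with an intensity trend in the prior variance, on genes with a mean of at least 1 over the libraries in each fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. On this scale the change of a gene near 0 is understated. The 3 comparisons between courses used day as a block. A 4th model asked whether the effect of leaving out BrdU differed between days 30 to 40 and days 6 to 22. The trend of the full course used day as a number over MEF and the 7 days, with the slope given per 10 days. MEF, day 40 of the full course and day 40 without BrdU were each compared with the 6 CiPSC libraries in 1 fit, in which the spread came from CiPSC alone and each lone library was assumed to vary like them. No fold is given for genes listed at 0 in every CiPSC library (645 of the genes tested), which show no spread there.

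The 27 gene lists were written before the data were examined. They cover fibroblast and mesenchymal, epithelial, pluripotency, extraembryonic endoderm, two-cell-like, post-implantation epiblast, Wnt beta-catenin target, p53 target, cell cycle, retinoic acid response, senescence and inflammatory secretion, interferon response, germline, DNA methylation machinery, AP-1/TEAD/RUNX, homeobox cluster, heat shock, cholesterol synthesis and glycolysis genes. Markers of other cells cover neural, macrophage and blood, skeletal and cardiac muscle, smooth muscle, endothelial, adipocyte, cartilage and bone, and trophoblast cells. Some genes stand in 2 lists (Zfp42, for example, is in the pluripotency and germline lists). Lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists of a comparison, and a list needed at least 5 tested members. Beside it stand camera with a correlation estimated from the residuals of the members, which also limits the test to the residual degrees of freedom of the fit, and fry. The PValue of fry asks whether a list's genes move on balance in 1 direction and PValue.Mixed whether they change in either direction. Neither compares the list with other genes. Members were also adjusted over the list alone. A list score is the mean of log2(value + 1) over members, and its differences between courses were tested over days with an exact sign-flip permutation test, whose smallest p is 0.0156 with 7 days and 0.0625 with 5 days.

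Genes named below were taken by a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls among called genes (in the course comparisons with the same sign on every day, leaving out predicted and mitochondrially encoded genes), the 3 members with the smallest p of each list that passed, and 16 fixed genes. Genes outside the rule are marked as chosen after their values were seen.

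Alternatives tried were a pseudocount of 0.25 or 5 in place of 1, no filter or a mean of at least 5, median-of-ratios scaling, no intensity trend, a minimum log2 change of 1, no day block, 1 fit over the 19 course libraries, days 6 to 30 only, a linear change of the BrdU effect with day, ranks of days, the trend without MEF, and leaving out each day or each CiPSC library in turn. Leaving out genes listed at 0 in every CiPSC library was added after seeing the data. The models were tested on simulated data with the moderated residual spread of each fit and 100 changed genes per size of change. At a log2 change of 1, 51% of them were recovered without BrdU, 38% without Chir, 50% in the direct comparison and 8% in the late against early comparison. At 2 these shares were 87%, 91%, 94% and 62%. Between 5.56% and 10.3% of the calls were false. The simulated noise was independent between genes and libraries, few genes were changed, and none of the changed genes had low values. These shares need not hold for serial days or for as many calls as in the real data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.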

Results

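Expression was compared across 26 mouse libraries. They are MEF (1 library), a chemical reprogramming course with all chemicals (7 libraries, days 6 to 40), a course without BrdU (7 libraries, the same days), a course without Chir (5 libraries, days 6 to 30) and CiPSC (6 libraries). Values are quantile-normalized scores whose totals lay between 4143561 and 4162600 in every library, so the depth behind them is unknown. No arm had replicates within a day. Errors of log2 changes and slopes are moderated standard errors from limma, which draw each gene's spread toward that of genes of like intensity. Between courses that spread is the one over days. Errors given for CiPSC values are standard deviations over its 6 libraries. A log2 change is that of value + 1.

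Over the full course, most epithelial, pluripotency and germline genes rose and most fibroblast and homeobox genes fell, list calls that did not hold with an estimated correlation (adjusted p = 0.0990 to 0.158). Pou5f1, a regulator of pluripotency, stood at 2 in MEF, 24 on day 12, 193 on day 22 and 1046 on day 40, against 4824 ± 409 in CiPSC. Nanog, which acts with it, stood at 2 on day 22, 422 on day 36 and 771 on day 40. Sox2 stood at 1, 371 and 660 on those days. Gata4, a regulator of primitive endoderm, went from 12 on day 6 to 2768 on day 22 and stood at 1557 on day 40. Cdh1, the epithelial cadherin, went from 2 in MEF to 2038 on day 40, and Thy1, a fibroblast surface marker, from 2167 to 255. In mm10, Pou5f1 lies on chromosome 17 from 35506018 to 35510772 and Nanog on chromosome 6 from 122707489 to 122714633. Sox2 lies on chromosome 3 from 34650405 to 34652461 and Gata4 on chromosome 14 from 63198922 to 63271692.

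**Figure D1:**
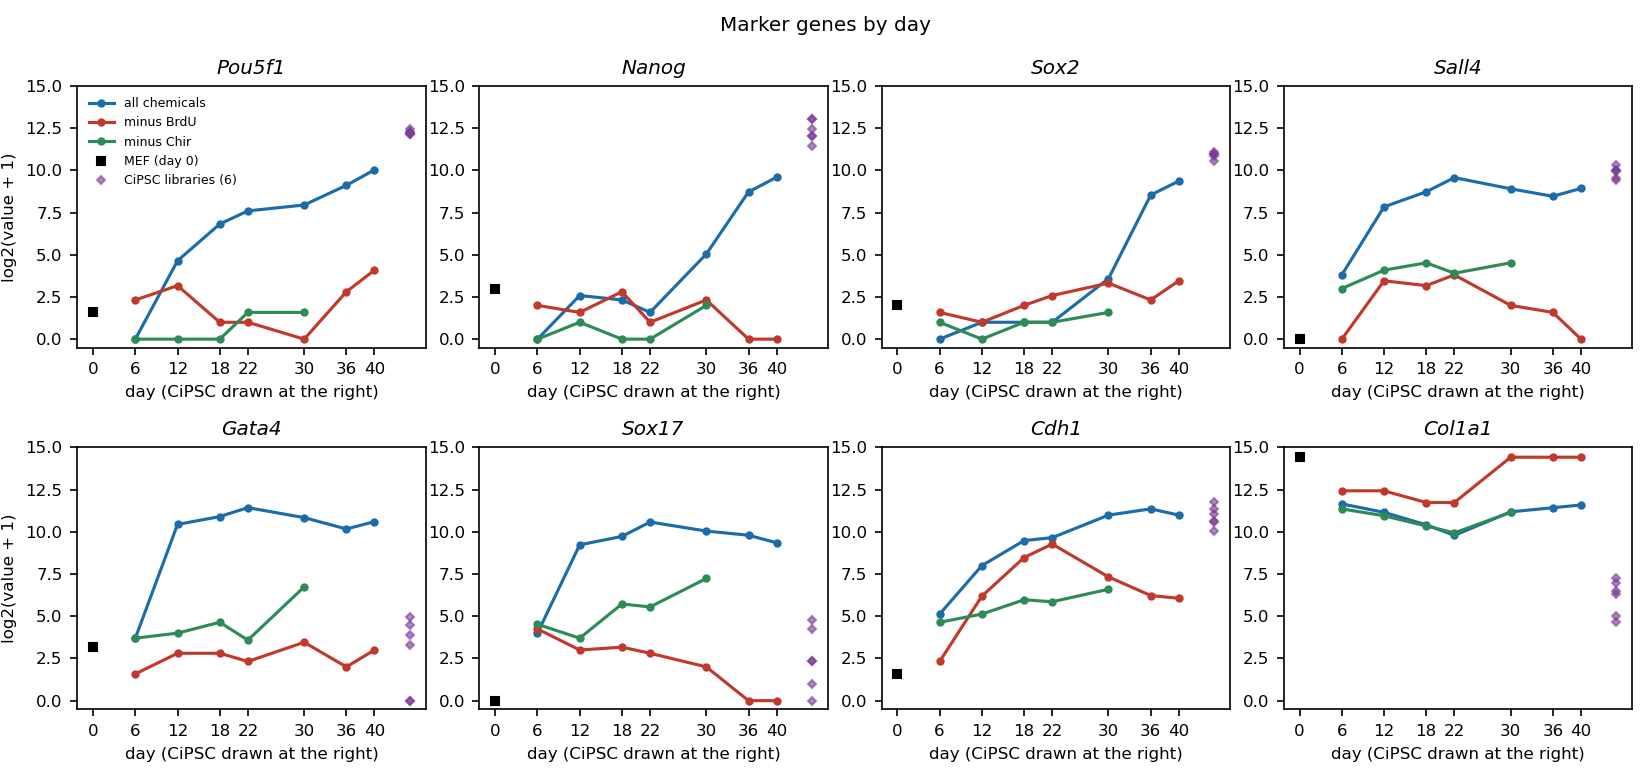
Values of 8 fixed genes by day, as log2(value + 1), with lines for the 3 courses, a square for MEF and diamonds for the 6 CiPSC libraries. In the full course Pou5f1 reached 1046 on day 40, against 16 without BrdU.

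A linear trend with day over MEF and the 7 days of the full course asked which genes had a slope with day (8 libraries, log2 change per 10 days). A called slope need not be a steady change. Sox2, for example, stood at 1 on day 22 and 371 on day 36. Epithelial genes rose in 19 of 20 cases (20 adjusted over the list alone; list adjusted p = 1.15e-14, adjusted p = 0.158 with an estimated correlation). Cldn7 (2.13 ± 0.19) and Tjp3 (2.03 ± 0.19), both of tight junctions, rose with Cdh1 (2.19 ± 0.33). Pluripotency genes rose in 24 of 32 cases (27 adjusted over the list alone; list adjusted p = 1.15e-14, adjusted p = 0.0990 with an estimated correlation). Among them were Pou5f1 (2.35 ± 0.30), Dppa4 (1.62 ± 0.20), Fbxo15 (2.12 ± 0.21) and Dppa5a (2.50 ± 0.39). Germline genes rose in 13 of 20 cases (16 adjusted over the list alone; list adjusted p = 4.47e-09, adjusted p = 0.0990 with an estimated correlation). They included Dazl (2.43 ± 0.34), an RNA-binding protein of germ cells, and Hormad1 (2.10 ± 0.31), a meiotic chromosome protein. Igfbp1, a secreted binding protein of insulin-like growth factors, had the largest slope of the named genes (3.48 ± 0.33), with 4962 on day 30 and 0 in MEF.

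Extraembryonic endoderm genes moved both ways over the full course, with 11 rising and 2 falling of 23 (15 and 2 adjusted over the list alone). Their list passed on the rising side (list adjusted p = 0.000106, adjusted p = 0.439 with an estimated correlation), with Hnf4a at 1.79 ± 0.20 and Afp at 2.04 ± 0.33, while Gata4 was not called (1.76 ± 0.53, adjusted p = 0.0530). Glycolysis genes rose in 7 of 18 cases (9 adjusted over the list alone; list adjusted p = 4.29e-06, adjusted p = 0.252 with an estimated correlation), with the glucose transporter Slc2a1 at 1.01 ± 0.09. Trophoblast genes rose in 5 of 12 (list adjusted p = 0.00121, adjusted p = 0.333 with an estimated correlation), with the transcription factor Gata2 at 0.58 ± 0.10. Two-cell-like genes rose in 5 of 12 (list adjusted p = 0.00590, adjusted p = 0.268 with an estimated correlation), with Zscan4f, of a family of near-identical copies, at 1.93 ± 0.34. Cell cycle genes rose in 6 of 29 (list adjusted p = 0.000219, adjusted p = 0.519 with an estimated correlation) and genes of the DNA methylation machinery in 3 of 10 (list adjusted p = 0.00903, adjusted p = 0.322 with an estimated correlation). Post-implantation epiblast genes rose in 4 of 11 (list adjusted p = 0.0264, adjusted p = 0.333 with an estimated correlation).

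Genes of the starting cells were among those that fell over the same course. Fibroblast and mesenchymal genes fell in 21 of 30 cases (24 adjusted over the list alone; list adjusted p = 3.03e-13, adjusted p = 0.101 with an estimated correlation). Snai2 (-1.29 ± 0.12) and Prrx1 (-1.22 ± 0.14), both mesenchymal transcription factors, were among them. Homeobox cluster genes fell in 22 of 29 (27 adjusted over the list alone; list adjusted p = 6.06e-14, adjusted p = 0.101 with an estimated correlation), with Hoxa5 at -1.28 ± 0.21. Senescence and inflammatory secretion genes fell in 8 of 19 (12 adjusted over the list alone; list adjusted p = 1.87e-07, adjusted p = 0.0991 with an estimated correlation), with the chemokine Ccl7 at -1.12 ± 0.19. Targets of p53 fell in 8 of 28 (12 adjusted over the list alone; list adjusted p = 7.56e-05, adjusted p = 0.257 with an estimated correlation), with Phlda3 at -0.33 ± 0.06. Cholesterol synthesis genes fell in 5 of 20 (list adjusted p = 0.00121, adjusted p = 0.554 with an estimated correlation). The adipocyte list passed on the falling side with no member called among 7 (list adjusted p = 0.0487, adjusted p = 0.361 with an estimated correlation). The scores of these 2 lists lay above MEF on day 6. Cholesterol synthesis stood at 8.41 in MEF, 9.53 on day 6 and 8.24 on day 40, and adipocyte genes at 5.18, 6.13 and 4.67. Macrophage markers stood high in the MEF library and low on day 6, with Lyz2 at 1686 and 58, C1qb at 498 and 4, and Csf1r, chosen after its values were seen, at 386 and 4. The macrophage list fell in 3 of 12 members (list adjusted p = 0.00121, adjusted p = 0.439 with an estimated correlation), a call that ended without MEF (adjusted p = 0.446).

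Of 16314 genes tested for a trend 2729 were called, 1519 rising and 1210 falling, and 17 of 27 lists passed, none with an estimated correlation. Leaving out day 36 left 1377 genes and day 40 left 1684. Without MEF the epiblast (adjusted p = 0.101), cell cycle (0.0860), DNA methylation (0.135) and trophoblast (0.0762) lists lost their call. The epiblast list also lost it without day 36 (0.0502) or 40 (0.0812), and the adipocyte list without any 1 of days 6 to 40 (lowest adjusted p 0.0505, without day 22). With fry, extraembryonic endoderm (0.0722), cell cycle (0.0799), cholesterol synthesis (0.145), macrophage (0.131) and adipocyte (0.0799) lost theirs. Nanog (1.99 ± 0.46) was called, but not without day 6 (adjusted p = 0.0571), 36 (0.0716) or 40 (0.0953). Sox2 (2.10 ± 0.50) was called, but not without the same days (adjusted p = 0.0564, 0.0778 and 0.106).

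**Figure D2:**
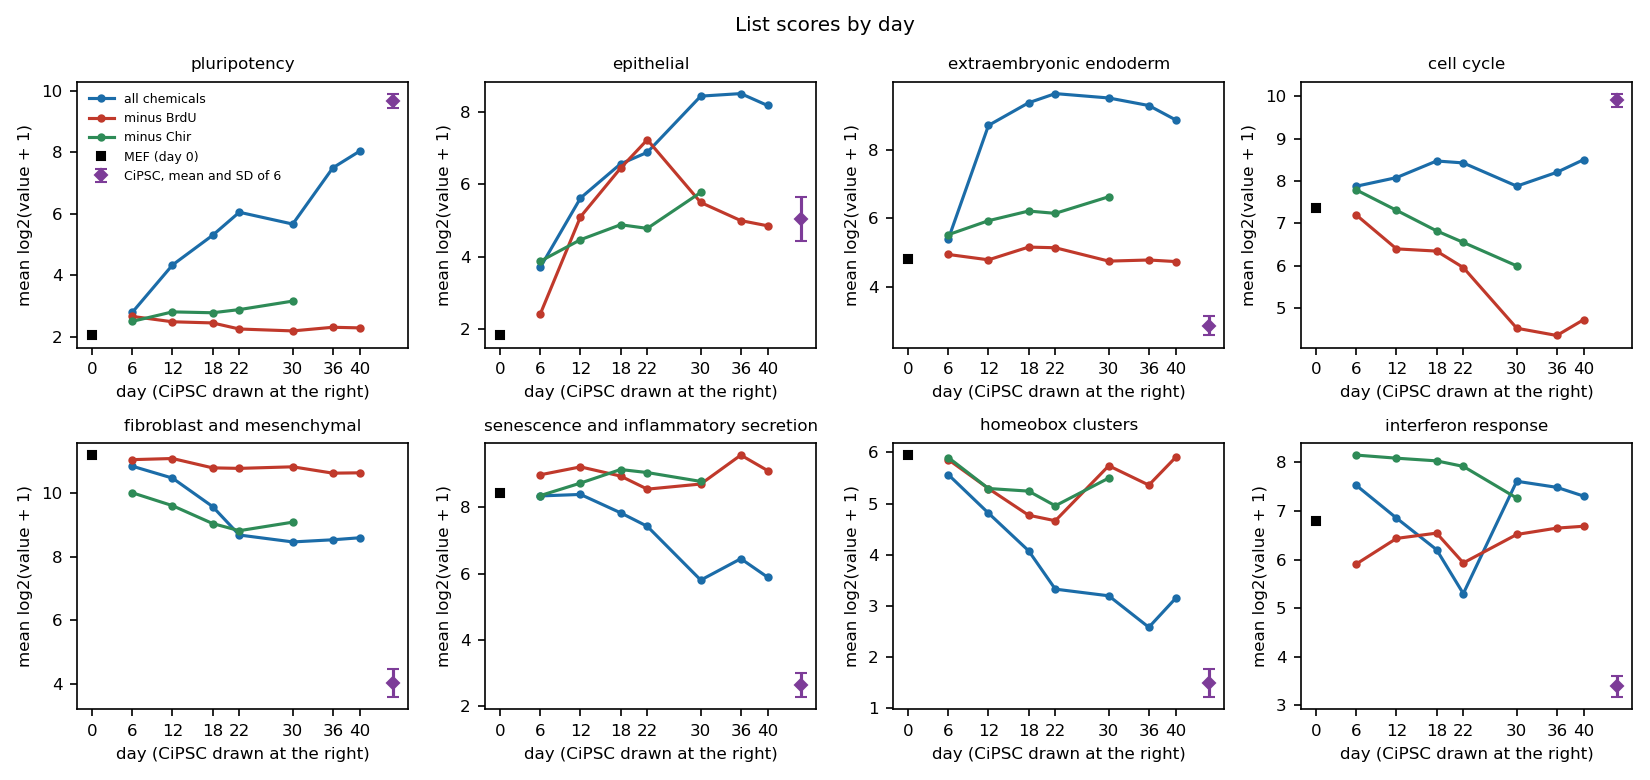
Mean log2(value + 1) of 8 gene lists by day in the 3 courses, with a square for MEF and a diamond with an SD bar for the 6 CiPSC libraries. The pluripotency score of the full course rose from 2.80 on day 6 to 8.04 on day 40, against 2.29 on day 40 without BrdU.

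Leaving out BrdU asked what the course needs that chemical for. Without it, most extraembryonic endoderm (21 of 23), pluripotency (23 of 32) and cell cycle genes (29 of 29) were lower and most fibroblast (22 of 30) and smooth muscle genes (7 of 9) higher (n = 7 days). These list calls did not hold with an estimated correlation (adjusted p = 0.4995 for each). The endoderm regulators Gata4 (log2 change -7.16 ± 0.71), Sox17 (-6.79 ± 1.04) and Foxa2 (-6.76 ± 0.86) were lower. So were Sall4, which maintains pluripotency (-6.03 ± 0.55), and Lin28a, an RNA-binding protein of early embryonic cells (-7.00 ± 0.75). Gata4, Foxa2, Sall4 and Lin28a were lower on every day, and Sox17 on 6 of 7 days. Saa3, an acute-phase protein, was higher (7.32 ± 0.74) and stood at the ceiling of 21988 on days 36 and 40, so its late values are lower limits. Igf1, a growth factor of mesenchymal cells (4.61 ± 0.39), and the extracellular matrix protein Mfap4 (5.32 ± 0.37) were higher too.

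Extraembryonic endoderm genes were lower without BrdU in 21 of 23 cases and higher in 1, with the same counts adjusted over the list alone (list adjusted p = 1.99e-08, adjusted p = 0.4995 with an estimated correlation). They included the basement membrane collagens Col4a1 (-3.32 ± 0.31) and Col4a2 (-3.55 ± 0.36), both at the ceiling on days 22 to 40 of the full course. Pluripotency genes were lower in 23 of 32 cases, the same adjusted over the list alone (list adjusted p = 6.37e-09, adjusted p = 0.4995 with an estimated correlation). Tdgf1 was at -5.95 ± 0.63 and Tdh, a threonine dehydrogenase of stem cells, at -6.71 ± 0.69. Zfp42 was listed at 0 on all 7 days without BrdU, against 206 on day 40 of the full course. Pou5f1 was lower (-4.54 ± 1.13), a call that ended with days 6 to 30 only (adjusted p = 0.0991). Nanog (-2.88 ± 1.41, adjusted p = 0.126) and Sox2 (-1.17 ± 1.07, adjusted p = 0.399) were not called over the 7 days.

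All 29 cell cycle genes were lower without BrdU, also adjusted over the list alone (list adjusted p = 1.03e-12, adjusted p = 0.4995 with an estimated correlation). Top2a (-3.72 ± 0.48), Ccna2 (-2.70 ± 0.32) and Cenpf (-2.84 ± 0.36), which act in mitosis, had the smallest p. DNA methylation machinery was lower in 8 of 10 cases and higher in 1 (list adjusted p = 0.00402, adjusted p = 0.4995 with an estimated correlation), with the maintenance factors Uhrf1 at -4.07 ± 0.69 and Dnmt1 at -1.17 ± 0.21. Epithelial genes were lower in 11 of 20 cases, the same adjusted over the list alone (list adjusted p = 0.000954, adjusted p = 0.565 with an estimated correlation). Among them were Epcam (-3.18 ± 0.37), Krt8 (-2.35 ± 0.40) and Cdh1 (-2.82 ± 0.57). Germline genes were lower in 11 of 20 (list adjusted p = 0.00119, adjusted p = 0.4995 with an estimated correlation), with Taf7l at -3.61 ± 0.78. Trophoblast genes were lower in 5 of 12 and higher in 1 (list adjusted p = 0.0265, adjusted p = 0.4995 with an estimated correlation), with Peg10 at -4.18 ± 0.74 (at the ceiling on day 40 of the full course), and the list call that ended without day 6 (adjusted p = 0.0523).

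Fibroblast and mesenchymal genes were higher without BrdU in 22 of 30 cases (25 adjusted over the list alone; list adjusted p = 1.33e-07, adjusted p = 0.4995 with an estimated correlation). The proteoglycan Lum (3.14 ± 0.28), the protease Fap (1.63 ± 0.22) and Zeb1 (1.63 ± 0.21) were among them, and Col1a1 (2.05 ± 0.32) lay at the ceiling on days 30 to 40. Smooth muscle genes were higher in 7 of 9 cases and lower in 1 (list adjusted p = 0.00133, adjusted p = 0.4995 with an estimated correlation), with the contractile proteins Acta2 at 3.94 ± 0.40, Tagln at 3.57 ± 0.39 and Tpm2 at 2.95 ± 0.32. Homeobox cluster genes were higher in 19 of 29 cases (27 higher and 1 lower adjusted over the list alone; list adjusted p = 7.83e-07, adjusted p = 0.4995 with an estimated correlation), with Hoxc10 at 2.90 ± 0.35. Senescence and inflammatory secretion genes were higher in 14 of 19 (15 adjusted over the list alone; list adjusted p = 3.07e-06, adjusted p = 0.4995 with an estimated correlation), with the chemokines Cxcl2 at 2.23 ± 0.26 and Cxcl1 at 1.83 ± 0.21. Targets of p53 were higher in 15 of 28 (list adjusted p = 0.000262, adjusted p = 0.526 with an estimated correlation), with Zmat3 at 1.30 ± 0.17. Cdkn1a, the cell cycle inhibitor, was called (0.77 ± 0.26), but not without day 18 (adjusted p = 0.0535), 22 (0.0575), 30 (0.0974), 36 (0.101) or 40 (0.103). Adipocyte genes were higher in 5 of 7 (list adjusted p = 0.00340, adjusted p = 0.4995 with an estimated correlation), with Pparg, the regulator of fat cell differentiation, at 1.25 ± 0.23. Cholesterol synthesis genes were higher in 10 of 20 and lower in 1 (list adjusted p = 0.0109, adjusted p = 0.4995 with an estimated correlation), with Nsdhl at 1.54 ± 0.14, and the list lost its call with no day block (adjusted p = 0.267).

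Interferon response genes were lower without BrdU in 7 of 22 cases and higher in 2 (list adjusted p = 0.0367, adjusted p = 0.672 with an estimated correlation), with the signal transducer Stat2 at -1.06 ± 0.14. That list lost its call without day 6 (adjusted p = 0.223), 30 (0.0738) or 36 (0.0555). Glycolysis genes were lower in 5 of 18 (list adjusted p = 0.0149, adjusted p = 0.672 with an estimated correlation), with Slc2a3 at -3.44 ± 0.55, a call lost without day 40 (0.0827). Two-cell-like genes were lower in 5 of 11 and higher in 1 (list adjusted p = 0.0432, adjusted p = 0.526 with an estimated correlation), with Usp17le, of a family of near-identical copies, listed at 0 on all 7 days against a mean of 6.29 in the full course. Their list lost its call without day 6 (0.0545), 30 (0.0738), 36 (0.0791) or 40 (0.123), and with a mean of at least 5 (0.471). With days 6 to 30 only, the two-cell-like (0.203), interferon (0.0939), glycolysis (0.384) and trophoblast (0.0939) lists lost theirs. Interferon did so with no day block (0.0521) and in 1 fit over 19 libraries (0.0694) as well, and two-cell-like with a pseudocount of 5 (0.0531). Lists that did not pass were post-implantation epiblast (1 higher, 5 lower and 5 neither, adjusted p = 0.151), retinoic acid response (10 higher, 4 lower and 2 neither, 0.108) and Wnt targets (8 higher, 5 lower and 7 neither, 0.666). Nor did AP-1, TEAD and RUNX factors (5 higher, 2 lower and 11 neither, 0.739), heat shock (1 higher, 3 lower and 8 neither, 0.666), neural (1 higher, 0 lower and 12 neither, 0.666) or macrophage genes (3 higher, 2 lower and 5 neither, 0.766). Skeletal and cardiac muscle (1 higher, 3 lower and 8 neither, 0.440), endothelial (1 higher, 4 lower and 3 neither, 0.159) and cartilage and bone genes (1 higher, 1 lower and 6 neither, 0.666) did not pass either. The median, mean and test differed in sign for Wnt targets (0.31, -0.11, upward) and heat shock (0.01, -0.11, downward).

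Without BrdU 6946 of 16308 genes were called, 3433 higher and 3513 lower, and 4514 of them had the same sign on every day. All libraries were set to 1 common distribution, which favours a balance of rises and falls in every comparison. Such a balance is thus not a result, and a change in total RNA could not be seen. A change of at least 1 held for 3816 genes, and days 6 to 30 alone gave 3735. Of 27 lists 17 passed, none of them with an estimated correlation. With fry, epithelial (0.0520), interferon (0.147) and glycolysis (0.146) lost their call. In the exact sign-flip permutation test of list scores, 10 lists had the same sign on all 7 days and the smallest possible p of 0.0156 (adjusted p = 0.0422). The test takes the successive days as independent, which they are not. Extraembryonic endoderm (mean difference -3.78, SD 1.49 over days), pluripotency (-3.29, 1.92), cell cycle (-2.57, 1.18), trophoblast (-1.89, 1.37), DNA methylation machinery (-1.40, 0.84) and two-cell-like scores (-1.25, 1.02) were lower. Smooth muscle (2.22, 0.61), senescence (1.85, 1.17), homeobox (1.56, 1.12) and fibroblast scores (1.52, 0.84) were higher.

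The effect of leaving out BrdU was then compared between days 30 to 40 and days 6 to 22 (3 against 4 days). Later, the effect of leaving out BrdU was shifted upward in 12 of 19 senescence and secretion genes, and downward in 14 of 20 epithelial, 12 of 18 glycolysis and 14 of 29 cell cycle genes. With an estimated correlation the first list kept its call (adjusted p = 0.0243) and the other 3 lost theirs (0.233, 0.291 and 0.371). The senescence and secretion score without BrdU was 8.55 to 9.22 on days 6 to 22 and 8.71 to 9.58 on days 30 to 40. In the full course it was 7.43 to 8.39 and then 5.81 to 6.45. The shift of that list thus lay mostly in a fall of the full course. Mmp3, a matrix metalloprotease, shifted by 6.81 ± 0.63, going from 914 on day 22 to 4224 on day 40 without BrdU and from 240 to 11 with it. The chemokine Ccl8 shifted by 6.02 ± 0.50 and Ptgds, a prostaglandin synthase, by 6.86 ± 0.88. Without BrdU, Cdh1 reached 620 on day 22 and stood at 66 on day 40. Thy1 shifted by -4.82 ± 0.78, with 1408 on day 22 and 28 on day 30 without BrdU, against 120 and 176 with it.

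Senescence and inflammatory secretion shifted upward in 12 of 19 genes (14 adjusted over the list alone; list adjusted p = 6.75e-10, adjusted p = 0.0243 with an estimated correlation), with Ccl7 at 2.97 ± 0.27. It was the 1 list that passed with an estimated correlation. Homeobox cluster genes shifted upward in 14 of 29 (23 adjusted over the list alone; list adjusted p = 3.53e-11, adjusted p = 0.233 with an estimated correlation), with Hoxa4 at 2.78 ± 0.46. Targets of p53 did so in 12 of 28 (19 adjusted over the list alone; list adjusted p = 1.45e-08, adjusted p = 0.248 with an estimated correlation), with Gdf15 at 2.93 ± 0.42 and Cdkn1a at 1.42 ± 0.22. Fibroblast genes shifted upward in 8 of 30 and downward in 2 (17 and 2 adjusted over the list alone; list adjusted p = 1.80e-06, adjusted p = 0.479 with an estimated correlation), with Twist1 at 2.51 ± 0.31 and Postn at 3.17 ± 0.40. Macrophage genes, high in MEF, shifted upward in 1 of 10 and the list did not pass (adjusted p = 0.753).

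Epithelial genes shifted downward in 14 of 20 cases (17 adjusted over the list alone; list adjusted p = 3.53e-11, adjusted p = 0.233 with an estimated correlation), with Cldn7 at -4.26 ± 0.47 and Ocln at -3.46 ± 0.37. Glycolysis did so in 12 of 18 genes (list adjusted p = 1.45e-08, adjusted p = 0.291 with an estimated correlation), with Slc2a1 at -2.98 ± 0.28 and Gapdh at -1.54 ± 0.26. Cell cycle genes shifted downward in 14 of 29 (24 downward and 1 upward adjusted over the list alone; list adjusted p = 1.01e-10, adjusted p = 0.371 with an estimated correlation), with Ccnb1 at -3.06 ± 0.49 and Bub1b at -3.17 ± 0.49. Trophoblast genes did so in 5 of 12 (list adjusted p = 0.000641, adjusted p = 0.158 with an estimated correlation), with Gata2 at -4.54 ± 0.43 and Plac1 at -4.06 ± 0.43. Two-cell-like genes did so in 4 of 11 (list adjusted p = 0.00289, adjusted p = 0.240 with an estimated correlation), with Zscan4f at -6.09 ± 0.73. Pluripotency genes shifted downward in 5 of 32 and upward in 1 (15 downward adjusted over the list alone; list adjusted p = 3.55e-06, adjusted p = 0.496 with an estimated correlation). Nanog shifted by -7.24 ± 1.58, a call that ended without day 36 (adjusted p = 0.0881) or 40 (0.0888). Germline (1 of 20 downward; list adjusted p = 0.000480, adjusted p = 0.371 with an estimated correlation), DNA methylation (3 of 10; list adjusted p = 0.0344, adjusted p = 0.496 with an estimated correlation) and endothelial lists (2 of 8; list adjusted p = 0.0411, adjusted p = 0.332 with an estimated correlation) also passed.

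Between the spans 2218 genes were called, 1145 upward and 1073 downward, and 13 of 27 lists passed. The count of genes was 713 without day 40, 806 without day 36, 1056 without day 12 and 1376 without day 18. DNA methylation lost its call without day 6 (adjusted p = 0.0740), 12 (0.0903), 36 (0.0547) or 40 (0.0716), and endothelial without day 6 (0.0898), 22 (0.0522) or 30 (0.0793). With fry, fibroblast (0.102), pluripotency (0.145), germline (0.0759) and DNA methylation (0.145) lost theirs, as did endothelial with no filter on low values (0.0588). Signs differed between median, mean and test for heat shock (0.06, 0.02, downward), adipocyte (-0.09, 0.40, upward) and cartilage and bone (-0.94, -0.56, upward), none of which passed.

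Leaving out Chir asked the same of the GSK3 inhibitor. Without it, 15 of 30 pluripotency, 17 of 23 extraembryonic endoderm, 10 of 20 epithelial and 21 of 29 cell cycle genes were lower, and 10 of 22 interferon, 5 of 7 adipocyte and 10 of 28 p53 genes higher (n = 5 days). These list calls did not hold with an estimated correlation (adjusted p = 0.451 for each). Axin2, a direct target of Wnt signalling, was lower (-2.12 ± 0.37), while Lef1 was not called (-0.75 ± 0.38, adjusted p = 0.176). F2, which encodes prothrombin (-6.18 ± 1.11), Pou5f1 (-4.77 ± 0.97) and Gata4 (-4.93 ± 1.02) were lower. The fatty acid carrier Fabp4 (3.70 ± 0.32) and Pparg (2.63 ± 0.20) were higher. So were Wfdc17, a secreted protein of the whey acidic protein family (4.94 ± 0.30), and Prl4a1, of the prolactin family with its near-identical copies (mean 40.8 without Chir, listed at 0 in the full course).

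Pluripotency genes were lower without Chir in 15 of 30 cases (18 adjusted over the list alone; list adjusted p = 8.70e-08, adjusted p = 0.451 with an estimated correlation). Klf5 (-2.76 ± 0.40), Tfcp2l1 (-3.66 ± 0.55) and Klf4 (-1.81 ± 0.25), regulators of naive pluripotency, were among them. Nanog (mean 0.8 against 8.6 in the full course, adjusted p = 0.0521), Sox2 (1 against 2.8, 0.605) and Dppa3 (1 against 5.2, 0.278) were not called. In the full course Nanog stood at 32 on day 30 and 422 on day 36, and Sox2 at 11 and 371. The course without Chir has no library after day 30, so it does not cover that rise. Extraembryonic endoderm genes were lower in 17 of 23 (list adjusted p = 4.52e-07, adjusted p = 0.451 with an estimated correlation). They included the uptake receptor Cubn (-4.51 ± 0.72), Hnf4a (-3.15 ± 0.58) and the laminin Lama1 (-4.23 ± 0.75). Epithelial genes were lower in 10 of 20 and higher in 1 (11 lower adjusted over the list alone; list adjusted p = 0.000155, adjusted p = 0.451 with an estimated correlation), with Cdh1 at -3.01 ± 0.52 and Cldn7 at -2.46 ± 0.51. Cell cycle genes were lower in 21 of 29 (25 adjusted over the list alone; list adjusted p = 3.67e-08, adjusted p = 0.451 with an estimated correlation), with the replication factor Mcm2 at -1.48 ± 0.22. DNA methylation machinery was lower in 5 of 10 (8 adjusted over the list alone; list adjusted p = 0.000561, adjusted p = 0.451 with an estimated correlation), with Tet1 at -2.83 ± 0.49. Germline genes were lower in 4 of 20 (0 adjusted over the list alone; list adjusted p = 0.00220, adjusted p = 0.451 with an estimated correlation), with Mael at -1.62 ± 0.47.

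Interferon genes were higher without Chir in 10 of 22 cases, the same adjusted over the list alone (list adjusted p = 0.000145, adjusted p = 0.451 with an estimated correlation). Isg15 (2.40 ± 0.51) and Ifit3 (2.51 ± 0.45) were among them. Adipocyte genes were higher in 5 of 7 (6 adjusted over the list alone; list adjusted p = 0.000159, adjusted p = 0.451 with an estimated correlation). Targets of p53 were higher in 10 of 28 (13 adjusted over the list alone; list adjusted p = 2.14e-05, adjusted p = 0.451 with an estimated correlation), with the death receptor Fas at 2.39 ± 0.39 and Perp at 2.52 ± 0.30. Homeobox genes were higher in 10 of 29 (15 adjusted over the list alone; list adjusted p = 8.24e-05, adjusted p = 0.451 with an estimated correlation), with Hoxb2 at 3.43 ± 0.59. Senescence and secretion genes were higher in 5 of 19 (10 adjusted over the list alone; list adjusted p = 0.000159, adjusted p = 0.451 with an estimated correlation), with Mmp3 at 2.45 ± 0.59. The macrophage list passed with 2 of 12 members higher (list adjusted p = 0.0227, adjusted p = 0.451 with an estimated correlation), Lyz2 at 3.30 ± 0.30 and C1qb at 1.87 ± 0.45, and lost its call without day 6 (adjusted p = 0.152) or with a mean of at least 5 (0.0828). The Wnt target list did not pass, with 4 higher, 4 lower and 12 neither (adjusted p = 0.337).

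Without Chir 4298 of 16248 genes were called, 2201 higher and 2097 lower, of which 3718 had the same sign on all 5 days. Leaving out 1 day gave 4994 genes without day 6, 3273 without day 12, 25 without day 18, 226 without day 22 and 2143 without day 30. Pou5f1 lost its call without day 18 (-4.26, adjusted p = 0.0782), 22 (-4.46, 0.0782) or 30 (-4.37, 0.0509), and Gata4 without day 18 (-4.60, 0.0803) or 22 (-4.20, 0.0755). With no day block Cldn7 (0.154), Mael (0.106) and C1qb (0.0916) lost theirs, as did Mmp3 with no filter on low values (0.0513). Of the 57 named genes that were called, 6 kept their call without day 18 (Prl4a1, Hsd3b6, Wfdc17, Fabp4, Lyz2 and Pparg), 16 without day 22 and 48 without day 30. In 1 fit over the 19 course libraries 6895 genes were called. Of 27 lists 12 passed, none with an estimated correlation and 4 of them with fry (pluripotency, DNA methylation, macrophage and adipocyte). The median, mean and test differed in sign for glycolysis (0.06, -0.27, downward), endothelial (0.30, 0.27, downward) and trophoblast (-0.37, -0.26, with fry upward), none of which passed.

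The courses without Chir and without BrdU were also compared directly, with no library of the full course. Without Chir 19 of 22 interferon and 15 of 29 cell cycle genes stood higher and 22 of 30 fibroblast genes lower than without BrdU (n = 5 days). These list calls did not hold with an estimated correlation (adjusted p = 0.436 for each). The antiviral genes Rsad2 (3.51 ± 0.23) and Isg15 (2.85 ± 0.29) were higher without Chir, as was the placental gene Psg17 (6.51 ± 0.41). Prl3d2, of the prolactin family, had a mean of 173 without Chir and was listed at 0 without BrdU. Lum (-4.09 ± 0.20), Mfap4 (-7.81 ± 0.31) and Cdh11, a mesenchymal cadherin (-3.61 ± 0.19, at the ceiling on day 6 without BrdU), were lower. The Wnt targets Axin2 (-1.60 ± 0.21) and Lef1 (-2.32 ± 0.24) were lower as well, but their list did not pass, with 5 of 20 higher and 9 lower (adjusted p = 0.221, adjusted p = 0.607 with an estimated correlation). Pou5f1 (-0.86 ± 0.76, adjusted p = 0.413) and Cdh1 (-1.08 ± 0.74, adjusted p = 0.295) were not called between the omissions. Pou5f1 had a mean of 0.8 without Chir and 2.8 without BrdU, so near 0 that a difference could hardly be seen.

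Interferon genes were higher without Chir than without BrdU in 19 of 22 cases and lower in 1, the same adjusted over the list alone (list adjusted p = 3.21e-08, adjusted p = 0.436 with an estimated correlation). Cell cycle genes were higher in 15 of 29 (list adjusted p = 6.28e-06, adjusted p = 0.436 with an estimated correlation), with Cdc20 at 1.71 ± 0.22 (not called with no day block, adjusted p = 0.152) and Mcm5 at 1.39 ± 0.22. Extraembryonic endoderm genes were higher in 11 of 23 and lower in 2 (13 higher adjusted over the list alone; list adjusted p = 0.00176, adjusted p = 0.436 with an estimated correlation), with Sox7 at 2.46 ± 0.33 and Gata4 at 1.94 ± 0.38, a call that ended in 1 fit over 19 libraries (2.08, adjusted p = 0.0731). Fibroblast genes were lower in 22 of 30 and higher in 2 (24 lower adjusted over the list alone; list adjusted p = 4.19e-09, adjusted p = 0.436 with an estimated correlation), with Col5a2 at -2.08 ± 0.17 and Col1a1 at -1.80 ± 0.31 (at the ceiling on day 30 without BrdU). Smooth muscle genes were lower in 7 of 9 (8 adjusted over the list alone; list adjusted p = 0.000871, adjusted p = 0.436 with an estimated correlation), with Myh11 at -2.26 ± 0.28. Two-cell-like genes were higher in 5 of 10 (6 adjusted over the list alone; list adjusted p = 0.0202, adjusted p = 0.436 with an estimated correlation), with Tdpoz4 at a mean of 17.2 and listed at 0 without BrdU. Targets of p53 were higher in 9 of 28 and lower in 1 (list adjusted p = 0.0245, adjusted p = 0.580 with an estimated correlation), with Gdf15 at 2.56 ± 0.13. Macrophage genes were higher in 3 of 12 (list adjusted p = 0.0416, adjusted p = 0.436 with an estimated correlation), with Lyz2 at 2.12 ± 0.38. Trophoblast genes were higher in 5 of 12 and lower in 2 (8 higher adjusted over the list alone; list adjusted p = 0.0468, adjusted p = 0.436 with an estimated correlation), with Gata3 at 2.71 ± 0.25.

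In this direct comparison 5176 of 16087 genes were called, 2725 higher and 2451 lower without Chir, with 2772 called without day 18 and 3141 without day 22. Of 27 lists 9 passed, none with an estimated correlation and 16 with fry. The macrophage list lost its call without day 6 (adjusted p = 0.0752) or 30 (0.0717), trophoblast without day 6 (0.121) or 30 (0.107), and p53 without day 22 (0.0615). With a mean of at least 5, trophoblast (0.0953) and two-cell-like (0.0539) lost theirs. With no day block, p53 (0.0737), macrophage (0.0765) and trophoblast (0.0901) did so, in 1 fit over 19 libraries p53 (0.164) and macrophage (0.0991), and with a pseudocount of 5 trophoblast (0.0663). Thy1 was not called over all 5 days (0.05 ± 0.70, adjusted p = 0.965) and was lower without Chir when day 30 was left out (-0.87, adjusted p = 0.0160). Signs of median and mean differed for retinoic acid response (-0.23, 0.24), homeobox (-0.08, 0.11), glycolysis (-0.07, 0.04) and skeletal and cardiac muscle (-0.05, 0.71). Germline genes had a negative median (-0.10) and fry pointed upward, and none of these lists passed.

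**Figure D3:**
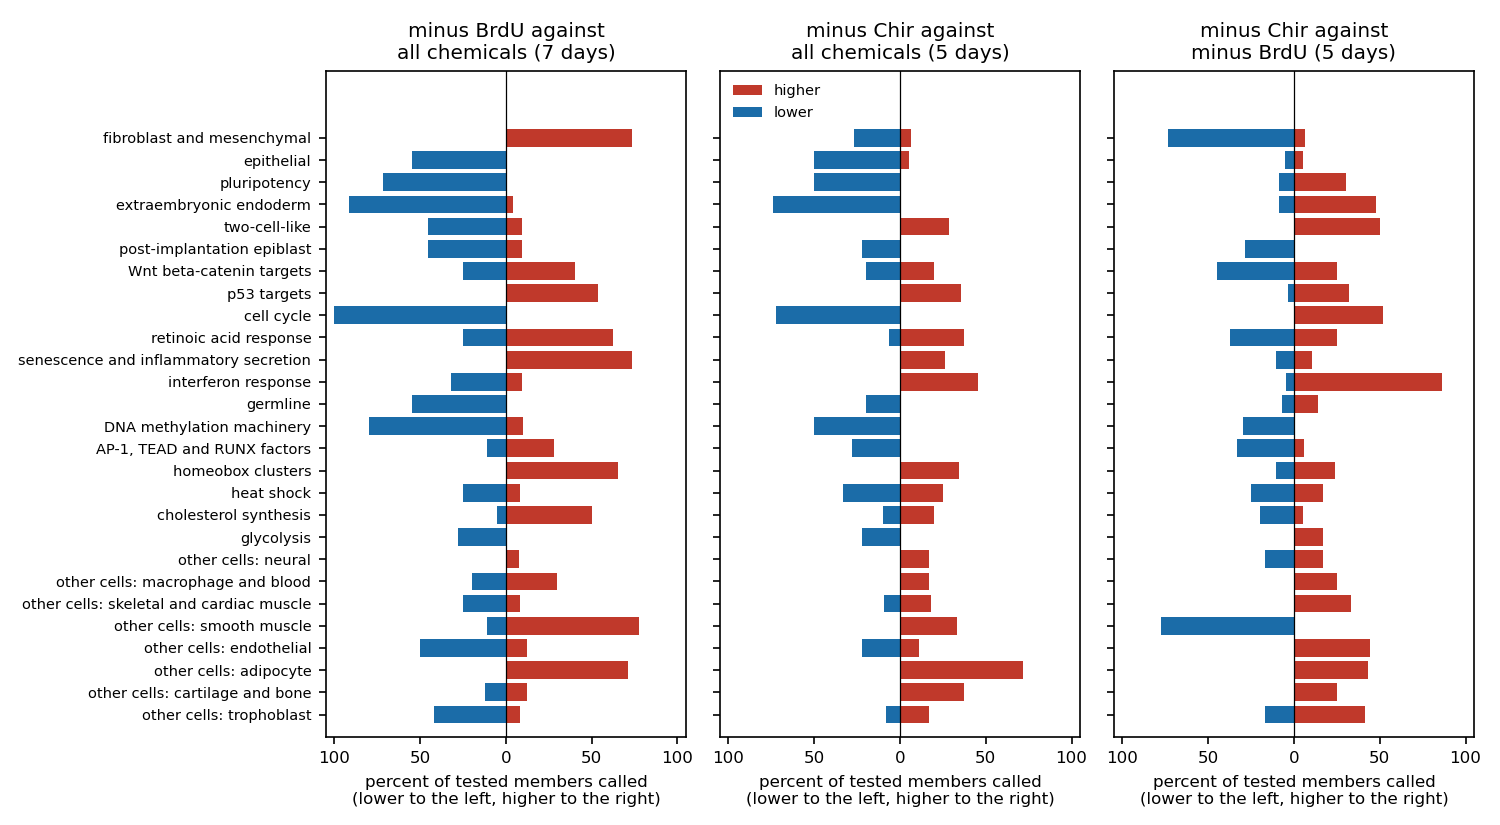
Percent of each list's tested members called higher (right) or lower (left) in the 3 comparisons between courses, with 7, 5 and 5 days. All 29 cell cycle genes were lower without BrdU, and 19 of 22 interferon genes were higher without Chir than without BrdU.

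Over days 6 to 30 the omissions shared called genes. Of 16095 genes tested in both, 443 were higher and 849 lower in both, and 182 went opposite ways, where independent calls would give 245, 247 and 492. Both omissions were measured against the same 5 libraries of the full course. The correlation of their changes across genes, which are not independent replicates, was 0.461 and lay below the median of 0.501 from 100 simulations of unchanged courses against shared controls. The covariance was 0.530, against 0.0834 in those simulations, which gave no gene called in both. With the omissions measured on disjoint days the covariance was 0.473 and 0.436 and the correlation 0.359 and 0.326, but fits of 2 or 3 days called no gene.

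MEF was compared with the CiPSC libraries (1 library against 6). Most pluripotency genes stood lower in MEF and most fibroblast, smooth muscle and inflammatory genes higher, and of these lists pluripotency lost its call with an estimated correlation (adjusted p = 0.0711). Pou5f1 stood at 2 in MEF against 4824 ± 409, Esrrb, a partner of Nanog, was listed at 0 against 2126 ± 248, and Dppa5a stood at 1 against 17428 ± 7065, with 4 CiPSC libraries at the ceiling. The proteoglycan Bgn and the actin Acta2 stood at the ceiling of 21988 in MEF, against 2.17 ± 5.31 and 7.17 ± 9.68. Macrophage markers stood beside these, with Ptprc at 178, Tyrobp at 144 and Adgre1 at 154 in MEF, all 3 listed at 0 in every CiPSC library.

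Pluripotency genes were lower in MEF in 31 of 32 cases (31 lower and 1 higher adjusted over the list alone; list adjusted p = 2.40e-16, adjusted p = 0.0711 with an estimated correlation). Cell cycle genes were lower in 28 of 29 (list adjusted p = 1.17e-11, adjusted p = 0.104 with an estimated correlation), with Mcm2 at -3.65 ± 0.20, and germline genes in 13 of 20 (list adjusted p = 4.24e-06, adjusted p = 0.191 with an estimated correlation), with Sycp3 listed at 0 in MEF against 117 ± 16.2. Epithelial genes were lower in 12 of 20 and higher in 1 (list adjusted p = 0.00145, adjusted p = 0.281 with an estimated correlation), with Cdh1 at -9.33 ± 0.60. Fibroblast genes were higher in 27 of 30 (list adjusted p = 4.40e-12, adjusted p = 0.0419 with an estimated correlation), with Col1a1 at the ceiling against 83.3 ± 50.1, and smooth muscle genes in all 9 (list adjusted p = 0.000235, adjusted p = 0.0419 with an estimated correlation), with Myl9 at 7.36 ± 0.93. Senescence and secretion genes were higher in 16 of 19 (list adjusted p = 4.94e-08, adjusted p = 0.0356 with an estimated correlation) and homeobox genes in 20 of 29 (list adjusted p = 8.93e-11, adjusted p = 0.0198 with an estimated correlation). Interferon genes were higher in 13 of 22 and lower in 1 (list adjusted p = 6.16e-05, adjusted p = 0.0356 with an estimated correlation), with Ifit3 at 6.68 ± 0.61. Macrophage genes were higher in 11 of 12 (list adjusted p = 9.68e-12, adjusted p = 0.0179 with an estimated correlation).

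Further lists passed between MEF and CiPSC. They were AP-1, TEAD and RUNX factors (11 higher, 2 lower and 5 neither; list adjusted p = 0.00183, adjusted p = 0.0570 with an estimated correlation), adipocyte (5 higher, 1 lower and 0 neither; list adjusted p = 0.00582, adjusted p = 0.104 with an estimated correlation) and glycolysis (0 higher, 8 lower and 10 neither; list adjusted p = 0.00917, adjusted p = 0.361 with an estimated correlation). DNA methylation (1 higher, 7 lower and 2 neither; list adjusted p = 0.00917, adjusted p = 0.136 with an estimated correlation) and post-implantation epiblast (1 higher, 7 lower and 3 neither; list adjusted p = 0.00917, adjusted p = 0.0970 with an estimated correlation) passed too. Retinoic acid response (5 higher, 1 lower and 9 neither; list adjusted p = 0.0363, adjusted p = 0.130 with an estimated correlation), extraembryonic endoderm (8 higher, 2 lower and 13 neither; list adjusted p = 0.0487, adjusted p = 0.134 with an estimated correlation) and two-cell-like (0 higher, 5 lower and 9 neither; list adjusted p = 0.0487, adjusted p = 0.626 with an estimated correlation) lay near the threshold. Extraembryonic endoderm lost its call without any 1 CiPSC library (adjusted p = 0.0524 to 0.0682), two-cell-like without CiPSC 3 (0.0576), 4 (0.0555) or 5 (0.0567), and retinoic acid response without CiPSC 5 (0.0567). Extraembryonic endoderm also lost it with no filter (0.0541), a mean of at least 5 (0.0750) or genes at 0 in CiPSC left out (0.0600). Two-cell-like lost it with a pseudocount of 5 (0.0895), no filter (0.0572), a mean of at least 5 (0.0573) or fry (0.0560). In all, 6592 of 16416 genes were called, 2940 higher in MEF and 3652 lower, 452 of them listed at 0 in every CiPSC library. Of 27 lists 18 passed, 6 of them with an estimated correlation. The median log2 change of all genes was -0.15. Median-of-ratios scaling removed that shift, and extraembryonic endoderm (0.0975) and retinoic acid response (0.0561) lost their call with it. Signs of median, mean and test differed for heat shock (-0.41, 0.00, downward) and neural genes (-0.49, -0.28, upward). With fry the sign differed from camera for p53 targets (fry downward, median 0.02) and skeletal and cardiac muscle (fry upward, median -0.43).

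Day 40 of the full course stood above CiPSC in 18 of 23 extraembryonic endoderm and 15 of 30 fibroblast genes (1 library against 6). With an estimated correlation the first list kept its call (adjusted p = 0.0196) and the second lost it (0.0817). Igfbp1 stood at 3630 and Cyp26a1, which degrades retinoic acid, at 558, both listed at 0 in CiPSC. Car4, a carbonic anhydrase, stood at 1792 against 0.667 ± 0.516. Pou5f1 (-2.20 ± 0.13), Sox2 (-1.54 ± 0.19) and Zfp42 (-2.60 ± 0.30) were lower than in CiPSC, as was Nanog (-2.74 ± 0.62), a call that ended without CiPSC 1 (adjusted p = 0.0525). Cdh1 (0.08 ± 0.60, adjusted p = 0.944), Sall4 (-0.95 ± 0.34, adjusted p = 0.0917) and Dppa3 (-0.71 ± 0.85, adjusted p = 0.589) were not called. The homeobox gene Cdx1 (1 against 219.8 ± 30.6) and the keratin Krt42 (0 against 186 ± 51) were among the largest falls.

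Extraembryonic endoderm genes were higher on day 40 in 18 of 23 cases (21 adjusted over the list alone; list adjusted p = 7.24e-10, adjusted p = 0.0196 with an estimated correlation), with Gata6 at 6.55 ± 1.40. Interferon genes were higher in 13 of 22 (16 adjusted over the list alone; list adjusted p = 8.80e-07, adjusted p = 0.0298 with an estimated correlation), with Usp18 at 6.74 ± 0.82. Gata4 (7.83 ± 2.21) lost its call without any 1 CiPSC library (adjusted p = 0.0524 to 0.0823), and Sox17 (6.91 ± 1.82) without CiPSC 1 (0.0742), 3 (0.0728) or 4 (0.0640). Fibroblast genes were higher in 15 of 30 (21 adjusted over the list alone; list adjusted p = 1.01e-08, adjusted p = 0.0817 with an estimated correlation), with Pdgfra at 9.65 ± 1.74. Senescence and secretion genes were higher in 10 of 19 (list adjusted p = 9.87e-06, adjusted p = 0.0689 with an estimated correlation) and homeobox genes in 10 of 29 (list adjusted p = 9.87e-06, adjusted p = 0.0626 with an estimated correlation). AP-1, TEAD and RUNX factors were higher in 10 of 18 and lower in 1 (list adjusted p = 0.00356, adjusted p = 0.0817 with an estimated correlation), with Fosb at 10.14 ± 2.12. Epithelial genes were higher in 6 of 20 (list adjusted p = 0.00116, adjusted p = 0.371 with an estimated correlation), with Krt19 at 10.23 ± 0.82. Pluripotency genes were lower in 22 of 32 and higher in 1 (24 lower adjusted over the list alone; list adjusted p = 6.26e-07, adjusted p = 0.231 with an estimated correlation), with Tdh at -3.04 ± 0.25 and Fgf4 at -2.85 ± 0.19. Cell cycle genes were lower in 23 of 29 (list adjusted p = 1.51e-09, adjusted p = 0.140 with an estimated correlation), with Rrm2 at -2.45 ± 0.21.

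Adipocyte (4 higher, 1 lower and 1 neither; list adjusted p = 0.00459, adjusted p = 0.125 with an estimated correlation), retinoic acid response (5 higher, 0 lower and 10 neither; list adjusted p = 0.0135, adjusted p = 0.121 with an estimated correlation) and smooth muscle genes (2 higher, 0 lower and 7 neither; list adjusted p = 0.0262, adjusted p = 0.140 with an estimated correlation) also passed on day 40. Retinoic acid response lost its call when genes at 0 in every CiPSC library were left out (0.0603), and smooth muscle with a pseudocount of 0.25 (0.0523). In all, 4515 genes were called, 2087 higher and 2428 lower (481 listed at 0 in CiPSC), and 12 of 27 lists passed, with 20 passing under fry. The median log2 change of all genes was -0.06, and 0.05 with median-of-ratios scaling. Signs of median and mean differed for heat shock (-0.19, 0.26), neural (-0.26, 0.60), muscle (-0.12, 0.57) and cartilage and bone genes (just under 0, 1.06). Wnt targets pointed downward with fry against a median of 0.76.

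Day 40 without BrdU was compared with CiPSC in the same way. Pou5f1 stood at 16, Nanog, Zfp42 and Sall4 were listed at 0, and Mmp3 stood at 4224 against 0.833 ± 2.04. Cdkn1a was higher (1.35 ± 0.31). Pluripotency genes were lower in 29 of 32 cases (30 adjusted over the list alone; list adjusted p = 8.35e-16, adjusted p = 0.0668 with an estimated correlation). All 29 cell cycle genes were lower (list adjusted p = 2.19e-16, adjusted p = 0.0668 with an estimated correlation), with Cdc20 at -6.92 ± 0.22. Mybl2, a proliferation factor in the pluripotency list, was at -8.09 ± 0.18. Fibroblast genes were higher in 27 of 30 (list adjusted p = 3.89e-10, adjusted p = 0.0668 with an estimated correlation), with Col1a1 at the ceiling against 83.3 ± 50.1, and homeobox genes in 23 of 29 (list adjusted p = 1.19e-09, adjusted p = 0.0504 with an estimated correlation). Senescence and secretion genes were higher in 16 of 19 (list adjusted p = 4.01e-08, adjusted p = 0.0601 with an estimated correlation) and smooth muscle genes in 8 of 9 (list adjusted p = 0.00632, adjusted p = 0.0668 with an estimated correlation), with Mylk at 8.32 ± 0.96.

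Lists that also passed upward without BrdU on day 40 were retinoic acid (9 higher, 1 lower and 5 neither; list adjusted p = 0.000881, adjusted p = 0.0668 with an estimated correlation), interferon (11 higher, 1 lower and 10 neither; list adjusted p = 0.000698, adjusted p = 0.0668 with an estimated correlation) and AP-1, TEAD and RUNX (12 higher, 2 lower and 4 neither; list adjusted p = 0.00632, adjusted p = 0.0668 with an estimated correlation). Adipocyte (5 higher, 0 lower and 1 neither; list adjusted p = 0.00172, adjusted p = 0.0668 with an estimated correlation), extraembryonic endoderm (8 higher, 2 lower and 13 neither; list adjusted p = 0.0254, adjusted p = 0.0980 with an estimated correlation) and macrophage (6 higher, 1 lower and 5 neither; list adjusted p = 0.00172, adjusted p = 0.0668 with an estimated correlation) were upward too. The macrophage call ended when genes at 0 in every CiPSC library were left out (adjusted p = 0.628). Lists that passed downward were germline (0 higher, 14 lower and 6 neither; list adjusted p = 1.26e-05, adjusted p = 0.215 with an estimated correlation), glycolysis (0 higher, 8 lower and 10 neither; list adjusted p = 0.00514, adjusted p = 0.349 with an estimated correlation) and DNA methylation (1 higher, 7 lower and 2 neither; list adjusted p = 0.00694, adjusted p = 0.122 with an estimated correlation). Two-cell-like (0 higher, 7 lower and 7 neither; list adjusted p = 0.0119, adjusted p = 0.588 with an estimated correlation) and post-implantation epiblast (1 higher, 7 lower and 3 neither; list adjusted p = 0.0265, adjusted p = 0.112 with an estimated correlation) were downward too. In all, 6806 genes were called, 3124 higher and 3682 lower (484 listed at 0 in CiPSC), and 17 of 27 lists passed. The median log2 change of all genes was -0.10, and 0.02 with median-of-ratios scaling. Signs of median, mean and test differed for Wnt targets (0.63, 0.53, downward), heat shock (-0.61, 0.13, downward) and endothelial genes (0.42, -0.40, upward). With fry the sign turned upward for neural (median -0.49) and cartilage and bone genes (median -1.04).

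Each library was placed between MEF and CiPSC by Pearson's r across genes, which are not independent replicates. With the mean CiPSC library the full course stood at 0.636 on day 6 (rho 0.674) and 0.788 on day 40 (rho 0.819), against 0.636 for MEF. The course without BrdU stood between 0.598 and 0.632 on its 7 days and the course without Chir between 0.621 and 0.643 on its 5 days. With MEF, the full course went from 0.865 on day 6 to 0.775 on day 40. The course without BrdU went from 0.880 on day 6 to 0.828 on day 22 and 0.880 on day 40.

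**Figure D4:**
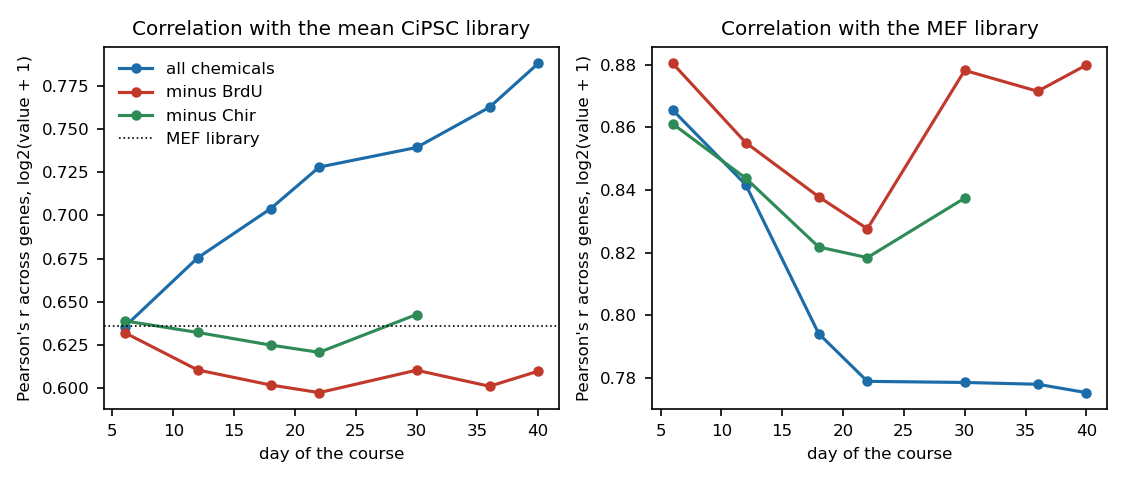
Pearson's r across genes of each course library with the mean CiPSC library (left, dotted line at MEF) and with MEF (right), by day. The full course reached 0.788 with CiPSC on day 40.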

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

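Of the tests in this part, the comparison with the late days of the full course was chosen only after the result was seen, and so was the rule that a set of fewer than 20 genes leaves a question open.

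Among 45 quantities looked at over the 6 CiPSC libraries, 2 had a library set apart from the others by a gap above the limit that Dixon's test sets for 6 values, where chance would give 2.25. CiPSC 2 had a p53 target score of 8.78 against 7.83 to 8.13 in the others (gap 0.690 of the range) and a cell cycle score of 9.60 against 9.94 to 10.02 (gap 0.811).

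The effect of leaving out BrdU differed between days 30 to 40 and days 6 to 22 for 2218 genes. Among the lists, the median shift was 1.42 for fibroblast, 1.65 for senescence and inflammatory secretion, 2.02 for homeobox and 0.94 for p53 target genes. It was -2.35 for epithelial, -2.81 for pluripotency, -1.67 for two-cell-like, -1.89 for cell cycle and -2.27 for germline genes. It was -0.54 for DNA methylation, -1.22 for glycolysis, -1.36 for endothelial and -2.91 for trophoblast genes. Of these lists only senescence and inflammatory secretion kept its call with an estimated correlation (adjusted p = 0.0243). Of the fixed genes, Nanog (-7.24), Sox2 (-5.17), Cdh1 (-3.07), Epcam (-1.99), Thy1 (-4.82) and Sall4 (-2.70) shifted downward, and Cdkn1a (1.42) upward. Col1a1 shifted upward by 1.69 and lay at the ceiling on all 3 late days without BrdU. Sox2 lost its call without day 6 (adjusted p = 0.0583), 12 (0.0698), 18 (0.0792), 22 (0.0616), 36 (0.148) or 40 (0.155), with no filter (0.0611) and with no intensity trend (0.0658). Sall4 lost it without day 12 (0.0934), 18 (0.0533), 30 (0.0501), 36 (0.0692) or 40 (0.118), with a pseudocount of 0.25 (0.0629) or 5 (0.116), no filter (0.0536) and no intensity trend (0.0554). Nanog lost it without day 36 (0.0881) or 40 (0.0888), Cdh1 without day 36 (0.0588) or 40 (0.0610) and Epcam without day 36 (0.0551). With a linear change with day, Cdh1 (0.0947) and Thy1 (0.0935) lost theirs.

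Other splits of the same libraries were run for the comparisons between courses. With the arms swapped within days, 1 of 64 splits (the real one) called 6946 genes without BrdU and the highest other called 4306, with only day 6 swapped. This argues against differences that arise by chance on separate days. No course was repeated, so a chance difference between cultures would recur on every day, and these splits cannot exclude it. With any 3 of the 7 days taken as late, 1 of 35 choices (the real one) called 2218 genes and the highest other 118. That other choice was days 6, 12 and 18, the opposite end of the course. Days are ordered, so a drift of either course with time would also favour a choice at an end. These choices therefore cannot exclude a chance drift. Without Chir (4298 genes, highest other 0, 1 of 16 splits as large) and in the direct comparison (5176 genes, highest other 0, 1 of 16) the splits are too few for a share under 0.05.

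Macrophage genes stood high in the MEF library, with 10 of 12 list members higher there than in any course library. Values from the authors' normalization alone are argued against, because 9 of the 12 lay above the upper quartile of MEF (236), where at most 2 were predicted. Macrophages in the MEF culture stay open. Among the MEF and course libraries, 6 of 9 further macrophage genes were highest in MEF, where at least 7 of 10 were predicted and 1 was not in the table. They were Mrc1 at 742, Ctss at 265, Spi1 at 106, Coro1a at 67, Fcgr3 at 164 and Csf3r at 20, which reached 32 in CiPSC. Cd74 (4 in MEF), Trem2 (88) and Lcp1 (534) were not highest in MEF. A candidate explanation is a share of macrophages in the primary culture that was lost by day 6, and with 1 MEF library it cannot be told apart from fibroblasts that express these genes.

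The course without BrdU moved toward MEF late, with a mean r across genes of 0.840 on days 12 to 22 and 0.876 on days 30 to 40. Handling that differed at late days in both courses stays open. A late mean r of the full course no higher than before was set to count against it. That mean changed by -0.0276 (from 0.805 to 0.777), lower but within 2 times its standard error over days (0.0189). Its values were 0.842, 0.794 and 0.779 on days 12 to 22 and 0.779, 0.778 and 0.775 on days 30 to 40. The error thus also holds the fall of this course over days 12 to 22. Regrowth of cells like the starting fibroblasts may account for the late move toward MEF: of 203 genes at 100 or more in MEF and at least 8-fold lower on days 12 to 22 of the full course, 70.4% (143) were higher late without BrdU, against 52.5% of all genes at 100 or more in MEF. The test had asked for at least 80% and against it for 60% or fewer, so regrowth cannot be told apart from cells that turn back toward a fibroblast state. Both are open too, as is a change of medium that reached only the course without BrdU, which was not tested. Smooth muscle scores without BrdU moved toward MEF (9.89), from 6.27 to 6.51 on days 12 to 22 to 8.18 to 8.77 on days 30 to 40. Cell cycle scores moved away from MEF (7.37), from 5.95 to 6.39 to 4.34 to 4.72. The latter argue against late cells that divided as in the MEF library, and growth itself was not measured.

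Genes at 2 or less on days 6 to 30 without BrdU and at 10 or more in both other courses numbered 2 (Mageb16 and Tbx20), against 1 with the course without Chir as the silent one and 0 with the full course. Dependence on BrdU in the medium cannot be told from so few genes. Reads shared between paralogs (100% of the 2 genes lie in families of 5 or more symbols, against 46.9% of genes tested) and GC content (median 42.6%, against quartiles of 43.9% and 53.98%) stay open for the same reason.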

How the results depend on the processing

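Leaving out genes listed at 0 in every CiPSC library was chosen only after the result was seen, and the other alternatives were planned. The cause of each change was not tested unless named. Requiring a log2 change of at least 1 left 3816 genes without BrdU, 2780 without Chir, 3040 between the omissions and 766 in the trend, which follows from its construction. With an estimated correlation the lists passing numbered 0 without BrdU, 0 without Chir, 0 between the omissions, 1 for late against early, 0 in the trend, 6 for MEF, 2 for day 40 and 0 for day 40 without BrdU. With fry 16 lists passed between the omissions and 20 for day 40 against CiPSC. Days 6 to 30 only gave 3735 genes without BrdU, and 1 fit over 19 libraries gave 6895 without Chir. Leaving out 1 day gave 25 (day 18) to 4994 (day 6) genes without Chir, with 226 without day 22 and 2143 without day 30. It gave 2772 (day 18) to 4783 (day 30) between the omissions, with 3141 without day 22. For late against early it gave 713 (day 40) to 2472 (day 22), with 806 without day 36, 1056 without day 12 and 1376 without day 18. In the trend it gave 1377 (day 36) to 2862 (MEF), with 1684 without day 40, and 1877 of the 2862 were also called with MEF. Signs turned for Thy1 between the omissions (0.05 over all days, -0.87 without day 30, up to 0.43 without day 22) and, with fry, for skeletal and cardiac muscle in MEF (adjusted p = 0.000988) and neural (0.00283) and cartilage and bone genes (3.06e-08) in day 40 without BrdU. Leaving out genes at 0 in CiPSC gave 6291, 3858 and 6468 genes for MEF, day 40 and day 40 without BrdU. Over all alternatives, gene results lost or gained a call in 36 and 0 cases without BrdU (1271 the same), 125 and 9 without Chir (772), 25 and 8 between the omissions (774), 78 and 14 for late against early (897), 80 and 6 in the trend (1274), 6 and 5 for MEF (1071), 13 and 3 for day 40 (889) and 3 and 2 for day 40 without BrdU (1020). List results did so in 38 and 3 cases without BrdU, 22 and 13 without Chir, 22 and 10 between the omissions, 24 and 18 for late against early, 44 and 4 in the trend, 31 and 6 for MEF, 12 and 16 for day 40 and 18 and 5 for day 40 without BrdU. A test on counts was planned and not run, because whole reads cannot be recovered from the deposited values.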

Other observations

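Of the values in this part, the retinoic acid genes other than Cyp26a1 and the values of Cyp26a1 on day 18 were chosen only after the results were seen.

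The retinoic acid list moved apart without BrdU (n = 7 days). Cyp26a1, which degrades retinoic acid, changed by -7.03 ± 0.61 on the log2 scale, with 4959 on day 18 of the full course against 38 without BrdU, and its paralog Cyp26c1 changed by -4.34 ± 0.62. Stra8, a meiotic gene induced by retinoic acid, changed by -3.84 ± 0.69. The binding proteins Crabp1 (3.57 ± 0.29) and Crabp2 (2.18 ± 0.35), the receptor gene Rarb (2.60 ± 0.47) and Meis2 (2.37 ± 0.25) were higher. In all 10 of 16 members were higher and 4 lower, and the list did not pass (adjusted p = 0.108).

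Several genes outside the fixed lists were among the largest changes. Without BrdU, the hexokinase-like Hkdc1 (-7.08 ± 0.91), the calcium-binding S100g (-6.86 ± 0.93) and the signalling protein Ihh (-6.57 ± 0.86) were lower, and Fibin (5.02 ± 0.38), Lmo3 (4.90 ± 0.60) and Serpina3g (4.62 ± 0.41) were higher. Without Chir, the receptor genes Kit (-4.40 ± 0.47), Pth1r (-4.66 ± 0.91) and Klb (-4.71 ± 0.86) and the transcription factor Pitx1 (-4.47 ± 0.68) were lower, calls that all ended without day 18 (adjusted p = 0.0525 to 0.0733). Those of Pth1r, Klb and Pitx1 also ended without day 22 (adjusted p = 0.0506 to 0.0709).

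Across genes, which are not independent replicates, Spearman's rho between gene length and log2 change was -0.0277 without BrdU (16143 genes) and -0.0903 without Chir (16083 genes). Since 3433 genes were higher and 3513 lower without BrdU, this signed rho does not show whether the size of the change goes with gene length, as a measure of the DNA that can take up BrdU. That stays open.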
